A study of Mus musculus with 12 samples.

How the data were processed

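The study measured RNA in mouse forebrain at embryonic days 12.5, 14.5 and 17.5, at birth (P0) and in adults (labelled P56), in wild-type animals and in animals heterozygous for a germline mutation of Chd8. It also mapped Chd8 on DNA by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type adult forebrain. Chd8 is a chromatin remodelling enzyme of the CHD family. Per the labels' protocols, the RNA libraries were stranded and made from polyadenylated RNA. They were read as single ends of 50 bp, except those of e12.5, which were read as paired ends of 100 bp.

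Per the labels, the authors' expression table holds log RPKM values (read counts scaled by gene length and library size). The deposited values are log2 values. The base was read from the values themselves: above a floor shared by several libraries, 2 to the power of the value moved in whole steps in most libraries. The table holds 12158 genes and 44 libraries. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.4.2a, BWA 0.7.13 and MACS2 2.10, with the genome build mm9. The read counter, the gene annotation, the gene filter and any normalization between RNA libraries are not given in the sources used here.

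The peak list is the authors' own. Per the deposited list, each summit has a score, a fold enrichment over input (a ratio) and a −log10 p and −log10 q from the peak caller. These values were used only to describe and rank summits within this list. The label calls the ChIP sample merged, while the peak names carry the name of a single wild-type sample, so whether replicates were pooled is open. There is 1 list and no replicate of it. The input sample was not analysed here apart from its part in the authors' ratio.

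The labels list 10 RNA samples, a wild-type and a heterozygous sample for each of 5 stages, while the table holds 44 libraries. Column names give the stage, and carry digit codes that no label explains. Each column therefore fits both samples of its stage, and none of the 44 columns could be matched to 1 sample. The codes were set beside Chd8 and Xist but not used to group libraries, and no genotype was assigned to any library. The planned comparisons of heterozygous with wild-type animals, of their interaction with stage, of wild-type stages and of gene lists between genotypes could not be run for this reason. The planned test of genes near Chd8 peaks was also not run, because no annotation of build mm9 was used here.

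In place of those tests, the libraries were described by stage. This plan was made after the table had been seen. It gives medians and ranges, with no mean, SD or p-value, because the libraries of a stage mix both genotypes. No gene or list was tested between stages. Splits of the libraries and a search for outlying libraries are given further below. Libraries were numbered within a stage in the order of the table, which is only a name. 2 pairs of stages were described, P0 against e14.5 and adult against P0, all read as single ends. A gene was called higher or lower when the ranges of the 2 stages did not overlap. Differences are of stage medians on the log2 RPKM scale, which holds an unstated prior count, so a fold understates the difference of a low gene. Both genotypes and both sexes are mixed in each stage, and the sexes in different proportions. Whether libraries of a stage came from separate animals is not stated per library, so ranges cover the spread between libraries only.

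Genes with a mean of at most −2 log2 RPKM over all libraries were left out (56), which left 12102. Before the data were examined, 17 gene lists and 17 lists of cell type markers were fixed, with a rule for the genes to name. The rule takes Chd8, the 10 genes with the largest difference in each direction among those with a mean of at least 0 log2 RPKM, up to 4 members of each list, and the 10 summits with the highest fold and −log10 q. Some genes that the rule takes are not reported here, while counts over all genes and over lists include them. It was written for tests, and was applied here to genes whose ranges did not overlap. A list's median difference was set among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. The 2 lists with fewer than 5 members in the table got no such percentile.

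The range comparison was tested on simulated libraries, with 200 genes shifted by known amounts among the 12102 genes. The shifted genes were drawn from those with a median above 0 at the earlier stage, so the shares below do not cover low genes. For P0 against e14.5, 58.2% of genes shifted by 0.5 log2, 92.5% of those shifted by 1 and 98.5% of those shifted by 2 came out apart in the right direction. For adult against P0 these shares were 47.8%, 80.6% and 97.0%. Of the 11902 unshifted genes, 0 came out apart in the first simulation and 1 in the second. Both stages of an unshifted gene were drawn alike, so these counts follow from the numbers of libraries. Random splits would part 0.144 and 1.96 of the 12102 genes. The simulated libraries held no difference of genotype, sex or batch, so the counts do not cover calls that such differences give. Their spread was that of the real libraries, with both genotypes and both sexes mixed, which can lower the shares above.

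Read totals are not given. Relative depth was estimated from low values, in 79 genes whose lowest value was shared by at least 3 libraries outside e17.5. The e17.5 libraries were left out of that definition after a first look had shown them off the steps. Their values were thus measured from a floor of other stages. The comparison cannot say whether they follow steps above a floor of their own. Between 5 and 59 low values per library were compared with whole multiples of 1 step, within 0.03 of a step. In 32 libraries at least 80% of the values lay on whole steps. The remaining 12 did not, and have no depth estimate.

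Alternatives for the stage comparisons were chosen after seeing the data: no filter on low values, a mean above 0, 2 pseudocounts, quantile normalization, median centring, and each library left out in turn. For peaks, a higher fold and a −log10 q of at least 5 had been planned. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9. Peak coordinates count from 1, on mm9. Summits closer than 100000 bp were joined into clusters, a distance chosen after the list had been seen.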

Results

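RNA was measured in 44 forebrain libraries, 8 from e12.5, 9 from e14.5, 10 from e17.5, 11 from P0 and 6 from adults. Forebrain was dissected from Chd8 heterozygous mice, which carry a disrupted copy of the gene, and from wild-type littermates. The column names do not say which library came from which genotype in terms that the labels explain, so no library was assigned a genotype and no comparison of genotypes was made. Values below are log2 RPKM, given as medians and ranges over the libraries of a stage. Relative depth, where the low values gave it, ran from 0.61 in e14.5 library 8 to 1.85 in adult library 1. No depth could be estimated for the 10 e17.5 libraries or for 2 of e12.5. The ratio of the sexes differed between stages: Xist, the RNA that silences an X chromosome in females, was above 0 in 6 of 8, 5 of 9, 5 of 10, 9 of 11 and 1 of 6 libraries from e12.5 to adult. The Y-linked gene Ddx3y was above 0 in the remaining ones, 2, 4, 5, 2 and 5.

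Chd8, the targeted gene, was present at every stage. Its median was 4.31 at e12.5 (range 3.90 to 4.96, 8 libraries), 4.01 at e14.5 (3.62 to 4.69, 9 libraries) and 3.94 at e17.5 (3.70 to 4.50, 10 libraries). The e17.5 values are less surely comparable, because few of their low values lie on whole steps of a read above the floor of other stages. At P0 it was 4.14 (3.69 to 4.60, 11 libraries) and in adults 3.72 (3.08 to 4.15, 6 libraries). The e12.5 libraries were read as paired ends of 100 bp and the others as single ends of 50 bp, so the e12.5 median holds the read type too. The ranges of neighbouring stages overlapped. Within a stage the highest library stood above the lowest by 1.74 times at e17.5 and by 2.1 times in adults, with the other stages between these. Because genotype was not assigned, these values do not check the labels.

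**Figure D1:**
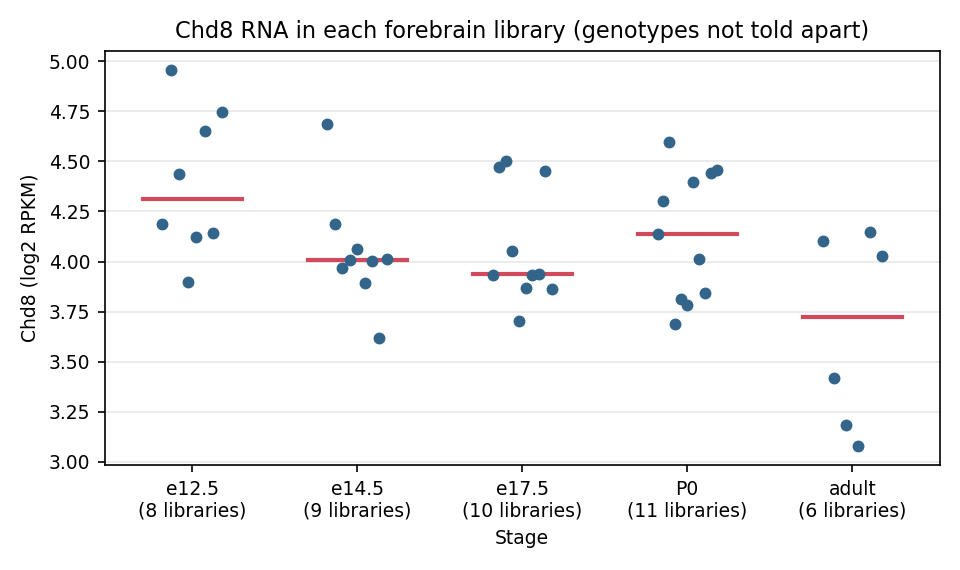
Chd8 RNA in log2 RPKM (vertical axis) by stage (horizontal axis); each point is 1 library and each bar the median of the stage. Stage medians lie between 3.72 in adults and 4.31 at e12.5, and the ranges of neighbouring stages overlap. Libraries of e12.5 were read as paired ends, those of the other stages as single ends.

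The first stage comparison asked how forebrain RNA at birth differed from that at e14.5. Most members of the astrocyte and synaptic lists were higher at P0, and most of the cell cycle, radial glia and intermediate progenitor lists lower. Gfap, an intermediate filament of astrocytes, had a median of 3.55 at P0 against −2.92 at e14.5, a difference of 6.47. The water channel gene Aqp4 differed by 5.04, and the postsynaptic calmodulin-binding gene Nrgn by 5.02, from 3.06 to 8.08. Other genes with large differences were Pla2g3 (4.52), the kinase gene Ptk2b (4.43), Thy1, a surface glycoprotein of neurons (4.25), Npas2 (4.21) and A230050P20Rik (3.79).

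At the low end stood the embryonic globin genes Hbb-y and Hba-x. Hbb-y had a median of 7.57 at e14.5, and Hba-x of 4.67, while at P0 their medians, −3.03 and −2.99, lay at the floor of the table, so no fold is given. The proneural transcription factor gene Neurog2 was lower at P0 by −4.34 (6.24 at e14.5 and 1.90 at P0). Nhlh1 differed by −3.68, the mitotic cyclin gene Ccnb1 by −3.54, Dct by −3.22, the cartilage collagen gene Col2a1 by −3.17, the condensin gene Ncapg by −3.12 and the growth factor gene Fgf15 by −3.11. The ribosomal protein gene Rps10 differed by −3.14. Ribosomal protein genes have many processed copies in the genome that can share reads, so their values are uncertain.

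Among the lists, every described gene for DNA replication and mitosis was lower at P0. In the list for G1/S and DNA replication, 25 of 25 members were lower, with a median difference of −1.71, among them Uhrf1 (−2.55), Cdc6 (−2.33), Mcm3 (−2.20) and E2f2 (−2.20). In the list for G2/M and mitosis, 22 of 22 were lower (median −2.36), among them Aurkb (−3.06), Bub1 (−2.98) and Cdc20 (−2.95). Both medians lay below those of all random lists of like expression (percentile 0.0). Of the 32 lists compared in this way, 14 lay within the central 95% of random lists between e14.5 and P0, and 7 between P0 and adult. Of 19 markers of radial glia and neural stem cells, 13 were lower and 1 higher (median −1.09), with Hmga2 at −3.92 and Sox3 at −2.67. Of 15 markers of intermediate progenitors and new neurons, 8 were lower and 1 higher (median −1.20), with Neurog1 at −5.55 and Eomes at −2.26. In the same libraries, only 5 of the 14 fixed blood cell genes were described. All 5 were lower (median −3.54, the value of Hbb-bh1), and Hbb-y, Hba-x and Hbb-bh1 had P0 medians at the floor. These few genes do not measure the amount of blood.

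Most members of the synaptic lists were higher at P0. Of 24 presynaptic and vesicle genes, 22 were higher and 0 lower (median 1.37), with Syn1 at 1.95 and Rims1 at 1.94. Of 25 postsynaptic genes, 23 were higher and 0 lower (median 1.46), with the NMDA receptor gene Grin1 at 2.89 and the kinase gene Camk2b at 2.52. Of 24 genes of REST, a repressor of neuronal genes, and its targets, 15 were higher and 2 lower (median 1.08), with Vgf at 2.99. Of 19 immediate early genes, which respond within minutes to neuronal activity, 12 were higher and 2 lower (median 1.58), with Egr1 at 3.59 and Npas4 at 3.04. Of 13 striatal markers, 10 were higher and 1 lower (median 1.25), with Penk at 3.49 and the dopamine receptor gene Drd2 at 1.92. Of 16 astrocyte markers, 11 were higher and 1 lower (median 1.01), with Apoe at 2.88. Of 14 genes of the oligodendrocyte lineage, 5 were higher and 0 lower (median 0.71), with Sox10 at 3.33 and Olig1 at 2.41.

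Of 11 upper-layer cortical markers, 5 were higher and 0 lower (median 0.76), with Mef2c at 3.01. Of 11 deep-layer markers, 4 were higher and 1 lower (median 0.26). Chromatin remodelling genes went in both directions, with 4 of 37 higher and 11 lower (median −0.22), among them Baz1a (−2.02), Actl6a (−1.95) and Hdac1 (−1.61). Of 40 splicing genes, 12 were lower and 1 higher, Rbfox1 at 2.03 (median −0.19). The count of higher ones was 3 without e14.5 library 1 or with median centring, and 2 without e14.5 library 5, P0 library 4 or P0 library 9, or with quantile normalization. Of 30 genes of the Wnt/beta-catenin pathway, 12 were lower and 3 higher (median −0.58), with Wnt8b at −2.98 and Myc at 1.51. Of 39 genes associated with autism, Chd8 left out, 14 were higher and 1 lower (median 0.16), with the sodium channel gene Scn2a1 at 2.21 and Foxp1 at 1.59.

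Over all 12102 genes, 2753 were higher and 2792 lower at P0 (11 libraries) than at e14.5 (9 libraries), 45.8% in all. With median centring 2921 were higher and 2580 lower, so the direction of the balance depended on the scaling. A random split of 20 libraries of these sizes would part the ranges of 0.00119% of genes. By 2-fold or more, 1334 were higher and 956 lower. The median difference over all genes was −0.04. These counts describe the stages with both genotypes mixed.

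The second stage comparison asked how adult forebrain differed from that at P0. Most members of the myelin, microglia, astrocyte and synaptic lists were higher in adults, and most of the cell cycle, intermediate progenitor and axon guidance lists lower. Scn4b, a sodium channel subunit, had a median of 6.65 in adults against −1.94 at P0, a difference of 8.58. The myelin genes Mag (6.97), Mal (6.80) and Mbp (6.09) were also among the highest, with the matrix gene Hapln4 (6.99). Vip and Pvalb differed by 6.66 and 6.52, Gm11549 by 6.26 and Wnt10a by 6.00. Vip and Pvalb are genes of interneurons, but of the 21 markers of inhibitory neurons 10 were lower and 5 higher (median −1.60), with Dlx2 at −3.20.

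The largest differences in the other direction were those of Draxin, an axon guidance gene (−7.15, from 5.17 to −1.98), and Cd24a (−7.09, from 9.19 to 2.11). St8sia2, which adds polysialic acid to cell adhesion molecules, differed by −6.42, and Gpc2 and P2rx2 by −6.05 each. Trim67 (−6.01), Aplnr (−5.97), Dpysl3 (−5.65), Mex3a (−5.62) and the matrix gene Tnc (−5.61) completed the 10. In each of these 10 genes adult library 1 lay above all other adult libraries, as for Draxin at 4.01, where the next was −1.74.

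Among the lists, 11 of 14 genes of the oligodendrocyte lineage and myelin were higher and 0 lower (median 3.89). Of 14 microglial markers, 12 were higher and 0 lower (median 1.84), with Tmem119 at 3.67 and P2ry12 at 2.73. Of 16 astrocyte markers, 11 were higher and 1 lower (median 1.81), with S100b at 5.63 and the glutamate transporter gene Slc1a2 at 4.24. Of 24 presynaptic genes, 20 were higher and 0 lower (median 1.08), with Slc17a7 at 4.24 and Snap25 at 3.83. Of 25 postsynaptic genes, 13 were higher and 0 lower (median 0.61), with Arc at 5.34 and Camk2a at 4.44. Of 19 immediate early genes, 11 were higher and 2 lower (median 1.95), with Egr4 at 4.53 and Fos at 3.73. Adult library 4 had the lowest level of this list, 1.37 relative to the mean of all 44 libraries against 2.56 to 3.23 in the other adults, and without it 14 were higher. Of 32 oxidative phosphorylation genes, 13 were higher and 1 lower (median 0.52), with Uqcrb at 1.68. From e14.5 to P0 this list had gone the other way, with 8 lower and 3 higher (median −0.26). Uqcrb had medians of 5.32 at e14.5, 3.50 at P0 and 5.18 in adults, and Ndufc1 of 6.36, 4.87 and 6.36. In these 2 genes the adult level was thus near that of e14.5. Of 13 striatal markers, 7 were higher and 3 lower (median 1.25), with Ppp1r1b at 2.76 and Isl1 at −3.23.

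Most members of the 2 cell cycle lists were lower again in adults. In the list for G2/M and mitosis, 16 of 22 members were lower and 0 higher (median −3.03), with Mki67 at −4.77 and Cenpf at −4.25. In the list for G1/S and DNA replication, 17 of 25 were lower and 3 higher (median −1.70), with Ccna2 at −3.57 and Rrm2 at −3.34. With 1 library left out, 16 to 22 of the G2/M list and 17 to 20 of the G1/S list were lower. Of 15 markers of intermediate progenitors and new neurons, 8 were lower and 0 higher (median −2.09), with the microtubule gene Dcx at −5.59 and Tubb3 at −2.58. Of 19 radial glial markers, 11 were lower and 2 higher (median −0.95), with Fabp7 at −4.64 and Nes at −2.79. Of 30 axon guidance genes, 17 were lower and 2 higher (median −1.06), with Robo1 at −2.79. In adult library 1 the G2/M list lay at −1.60 relative to the mean of all 44 libraries, against a median of −3.99 for the adults.

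Several further lists held more lower than higher members in adults. Of 40 splicing genes, 23 were lower and 0 higher (median −0.67), with Tra2b at −2.17 and Ptbp2 at −1.83. Of 37 chromatin remodelling genes, 20 were lower and 2 higher (median −0.71), with Smarce1 at −2.11 and Hdac2 at −1.46. Of 30 genes of the Wnt/beta-catenin pathway, 15 were lower and 5 higher (median −0.81), with Myc at −3.80 and Dkk3 at 2.82. Of 19 cholesterol synthesis genes, 10 were lower and 0 higher (median −0.81), with Sqle at −1.57. Of 39 autism-associated genes, 6 were higher and 9 lower (median −0.30), with Shank3 at 1.68 and Auts2 at −1.82. Without adult library 1, 17 of them were lower, and with quantile normalization 2 were higher.

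**Figure D2:**
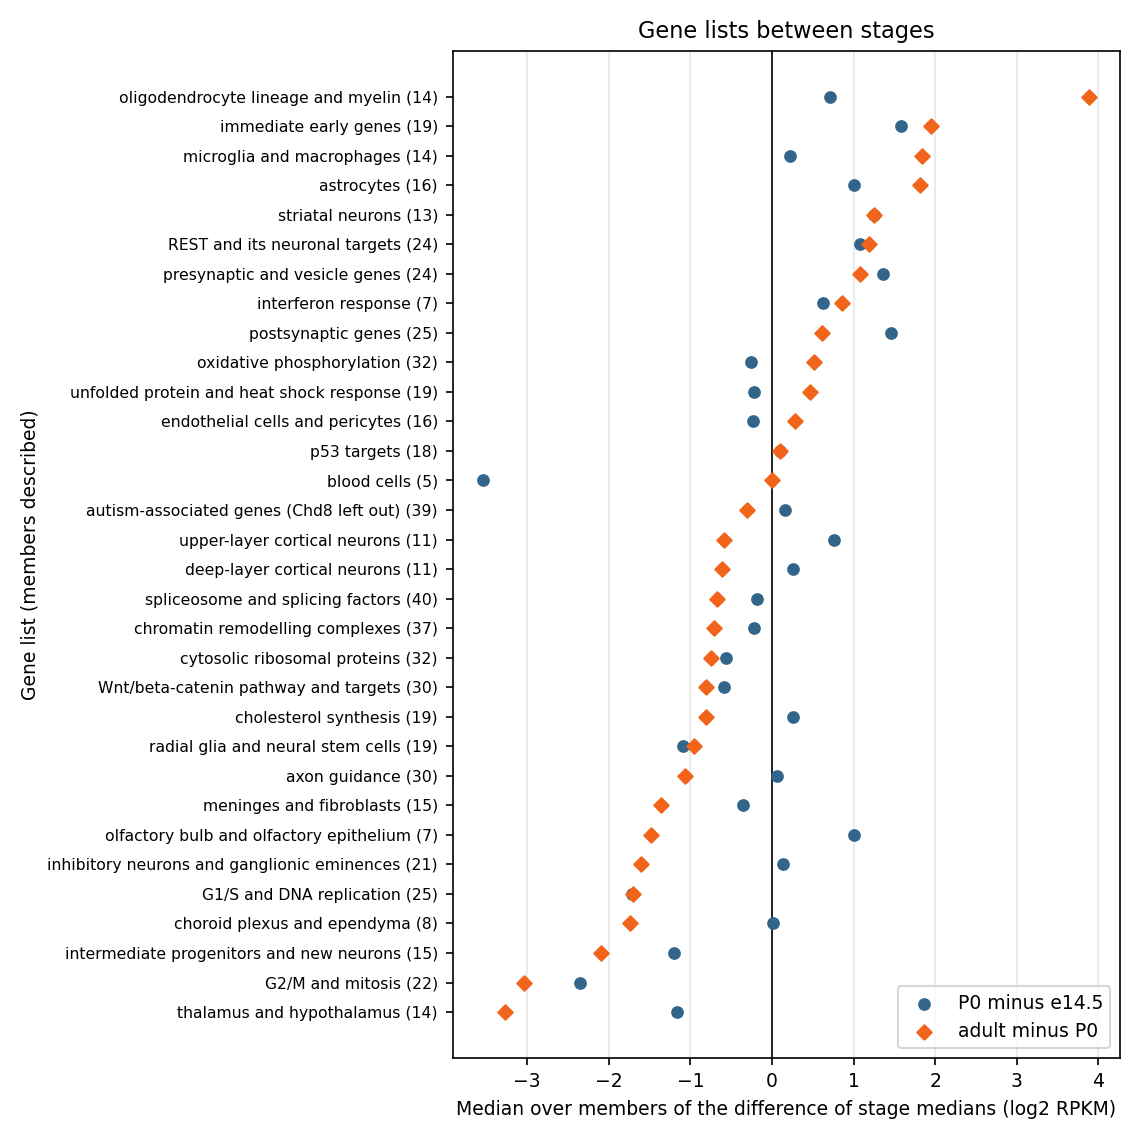
Median difference over the members of each gene list, in log2 RPKM (horizontal axis), for P0 minus e14.5 (circles) and adult minus P0 (diamonds), with the number of members described in brackets; lists under 5 members are not drawn. The myelin list stands at 3.89 between P0 and adult, and the G2/M list at −2.36 and −3.03.

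Over all genes, 3540 were higher and 3052 lower in adults (6 libraries) than at P0 (11 libraries), 54.5% in all. A random split of these sizes would part the ranges of 0.0162% of genes. By 2-fold or more, 1962 were higher and 1597 lower. The balance depended on the scaling: 3069 were higher and 3649 lower with quantile normalization, and 3203 higher and 3501 lower with median centring. Xist was above 0 in 1 of the 6 adult and 9 of the 11 P0 libraries, so sex and stage overlap here.

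1 adult library stood apart from the others. In 155 genes at least 3 log2 units higher at P0 than in the other adults, adult library 1 lay 37.8% of the way from adult to P0, with an interquartile range of 28.6 to 47.5%. The medians of the other 5 adult libraries, each against the rest, lay between −0.82 and 0.55%. Without adult library 1, 3771 genes were higher and 3635 lower in adults than at P0.

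**Figure D3:**
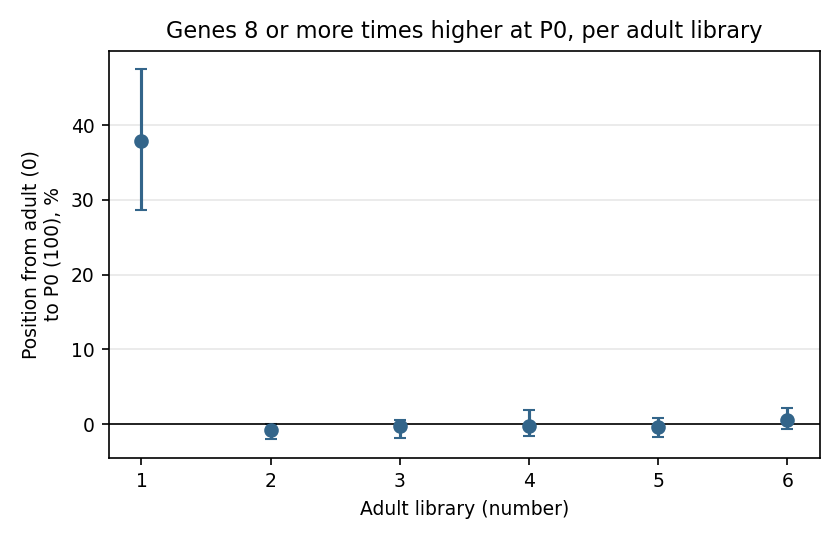
Position of each adult library (horizontal axis) between adult (0%) and P0 (100%) in genes at least 3 log2 units higher at P0 than in the remaining adult libraries (vertical axis, %); points are medians over genes and bars the interquartile range. Library 1 lies at 37.8%, and the others between −0.82 and 0.55%.

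The ChIP-seq list asked where Chd8 sat on DNA in wild-type adult forebrain. It held 467 summits in 216 intervals on mm9, with no replicate list, and no gene annotation of that build was used here. Fold enrichment over input ran from 3.14 to 42.57, with a median of 5.18, and the lowest −log10 q was 5.49. The 10 summits with the highest fold were also the 10 with the highest −log10 q, and all lay in mitochondrial DNA. The first of them, at position 4065 of chromosome M in an interval from 1 to 6597, had a fold of 42.57 and a −log10 q of 615. The tenth, at position 13625 in an interval from 10833 to 16299, had a fold of 37.13.

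The summits were unevenly spread. A cluster on chromosome 1 from 90108116 to 90207370 held 157 summits (33.6%), with folds up to 8.07. A cluster on chromosome 11 from 3001358 to 3100168 held 98 (21.0%), with folds up to 26.59. Both together held 54.6% of the list. An interval on chromosome 17 from 39979820 to 39985932 held 8 summits, with folds up to 36.71. Mitochondrial DNA, unplaced sequence, the first 4000000 bp of a chromosome and other clusters of 5 or more summits held 374 summits (80.1%).

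The remaining 93 summits lay in clusters of 1 to 4, with a median fold of 4.59. Among these, the highest fold was 21.50, in an interval on chromosome 9 from 35112624 to 35113267. An interval on chromosome 15 from 74915814 to 74917632 reached 18.86. Single intervals on chromosome X (109484282 to 109484882), chromosome 5 (147072414 to 147073092) and chromosome 2 (181651972 to 181652759) reached 14.36, 13.93 and 13.51. These intervals were chosen after their values were seen. Counts of summits with a fold above the list's median are 232 by construction.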

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

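The tests of explanations in this part were chosen after the values had been seen. Each stage of 4 to 10 libraries was searched for a highest or lowest library far from the rest. The search covered Chd8, the gene lists and 3 measures of the libraries, where each had values. Named genes, 250 of the 392 sets of values, were searched only at e14.5 and in adults. Of the 392 sets, 73 held such a library, where chance would give about 19.6, and 52 of the 73 were adult library 1. Of these 52, 45 came from genes named for a difference between adult and P0, so the sets are not independent. Chd8 had none in 4 stages. P0, with 11 libraries, was not searched.

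Adult library 1 lay far above the other adult libraries in genes that were lower in adults than at P0. Among the genes with the largest differences and the markers of axon growth and of new and inhibitory neurons these were Draxin (4.01), Cd24a (7.72), St8sia2 (4.59), Gpc2 (5.11), P2rx2 (0.85), Trim67 (4.54), Aplnr (1.84), Dpysl3 (7.66), Mex3a (4.30), Tnc (3.70), Dcx (6.15), Tubb3 (9.64), Mfap4 (2.67), Epha3 (2.82), Robo1 (4.39) and Dlx2 (3.56). Among genes of dividing cells and progenitors they were Ccna2 (2.58), Rrm2 (2.80), Uhrf1 (1.42), Mcm3 (2.16), Mki67 (1.62), Cenpf (0.21), Ckap2l (1.45), Aspm (−0.39), Fabp7 (8.32) and Nes (3.58). Others were U2af1 (3.77), Smarce1 (4.43), Ash2l (4.47), Hdac2 (6.61), Myc (3.34), Sfrp1 (3.52), Sp5 (−0.99), Aen (3.26), Mdga1 (3.45) and Pou3f2 (3.78). The cholesterol genes Sqle (5.84) and Fdps (5.22) and the meningeal genes Nid1 (2.33) and Bgn (3.83) did the same. It lay below the others in Mag (6.05), H2-K1 (3.62), B2m (6.45), Slc1a2 (7.52) and Itgam (2.18), all higher in adults than at P0.

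The levels of whole lists, relative to the mean of all 44 libraries, gave the same picture in that library. They were −1.35 for G1/S and DNA replication, −1.60 for G2/M and mitosis, −0.51 for the Wnt/beta-catenin pathway, −0.64 for intermediate progenitors and new neurons and −0.59 for inhibitory neurons. Each was the highest of the 6 adult libraries. Its median log2 RPKM was 3.75 and its relative depth 1.85, where the next were 3.70 and 1.16.

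A share of RNA like that of forebrain at P0 or e17.5 may account for adult library 1. In 155 genes at least 3 log2 units higher at P0 than in the other adults, it lay 37.8% of the way from adult to P0 (interquartile range 28.6 to 47.5%), and with e17.5 as the young stage 33.4% (29.0 to 38.1%). A share of 37.8% would lower adult genes by −0.69 through dilution, and 286 such genes were lower by −0.61 (interquartile range −0.74 to −0.47). With e17.5 these were −0.59 and −0.58 (−0.73 to −0.44). The e17.5 values are less surely comparable with the others. Xist limits the source of such a share. It was −6.63 in adult library 1, against 4.56 to 5.91 in the 9 P0 libraries where it was above 0. The share would have to come from tissue without Xist, as in 2 of 11 P0 and 5 of 10 e17.5 libraries. RNA of e14.5 forebrain stays open: its share would be 13.9% (9.71 to 25.9%), with dilution of −0.15 to −0.43, and adult genes were lower by −0.53 (−0.68 to −0.39). For RNA of e12.5 forebrain, a share of 5.29% (2.76 to 11.4%) gives −0.04 to −0.17, while adult genes were lower by −0.44 (−0.61 to −0.29). These values argue against it, but less surely. The e12.5 libraries were read as paired ends of 100 bp, so their share holds the read type too. A raised background or another depth is argued against, since 178 genes low at both ages were shifted by 0.12 (upper quartile 0.34), while the young genes were shifted by 2.43 (lower quartile 2.02). A less mature animal cannot be told apart from a mixture, because there is no stage between P0 and adult; the interquartile range of the adult genes' shifts was 0.27 wide, against 0.32 to 0.57 in the other 5 adult libraries.

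The remaining 21 values came from 11 list levels, 9 genes and 1 library measure. In adult library 4, immediate early genes were lowest at 1.37 and upper-layer cortical neurons at −0.36, and Ndufa2 was highest at 7.12. In adult library 6 postsynaptic genes were highest at 1.72, and in adult library 3 Bdnf at 4.06. In e17.5 library 6 inhibitory neuron markers were highest at 0.56 and those of intermediate progenitors and new neurons lowest at −0.029. The meningeal list was lowest in e17.5 library 10 at −1.15, and the median log2 RPKM was highest in e17.5 library 2 at 3.67. In e14.5 library 3 the choroid plexus list was lowest at −0.68, the meningeal list at −0.17 and the red cell gene Slc4a1 at −0.69. In e14.5 library 2 the G2/M list was lowest at 0.88 and Ncapg at 2.84, and S100b was highest at −0.72. In e14.5 library 7 Shank2 was lowest at 1.55, Grin2b at −1.52 and Sox5 at 4.18, and in e14.5 library 1 Fdft1 at 5.23. The list of p53 targets was highest in e12.5 library 2 at 0.39, and the thalamic and hypothalamic list lowest in e12.5 library 7 at 0.55.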

How the results depend on the processing

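All settings for the stage comparisons were chosen after the data had been seen; those for the peaks were planned. Between P0 and e14.5, the counts of genes with ranges apart were 2647 to 2921 higher and 2580 to 2897 lower over the other settings. As deposited 49.6% of them were higher, with quantile normalization 48.2% and with median centring 53.1%, so that scaling turned the balance. With 1 library left out, the counts were 2756 to 2874 higher and 2796 to 3046 lower. Between P0 and adult, the counts were 3069 to 3579 higher and 3027 to 3649 lower over the other settings, and 3552 to 3771 higher and 3063 to 3635 lower with 1 library left out. The highest of these came without adult library 1, with 3771 higher and 3635 lower. More genes were higher than lower in adults as deposited (53.7% of those apart), but 45.7% were higher after quantile normalization and 47.8% after median centring, so here too the balance depends on the scaling. Leaving out a library can only keep or part ranges, and a pseudocount keeps the order of the values, so neither says that the counts are stable. Of the differences of named genes, 1 of 500 under the 2 scalings, the only settings that can end a call, no longer had ranges apart (Pvalb at P0 against e14.5, with quantile normalization). Of the list counts, 18 of 272 under the 2 scalings, 5 of 272 under the 2 filters and 33 of 2516 with a library left out moved by over 1.5 times. Without a library, the moves not given beside their list were of counts of 0 or 1 that became 1 or 2.

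The number of Chd8 summits was 232 of 467 above the list's median fold, which follows from its construction, and 467 at a −log10 q of at least 5, a limit that removes nothing. Of 100 splits of the 20 libraries of P0 and e14.5, 1, the real one, gave as many genes with ranges apart (5545); the highest other gave 1. For adult and P0 it was again 1 of 100, with 6592 genes against 8. A split that mixes the stages makes the ranges of differing genes overlap. These values therefore say only that both counts go with the grouping by stage. These splits do not part stage from sex or batch.

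No paired analysis was possible because no library was matched to a sample and the result comes from no test. Apart from these splits and the search for outlying libraries, no test was made on libraries mixed in genotype, by choice. Left out with it were library weights, a fit without a trend, sex as a covariate, a replicate block, fits per stage or with a stage left out, an additive model, list tests with an estimated correlation, and rotation tests of lists. Read totals are not given, so counting error per gene is unknown, and low genes are the least certain.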

Other observations

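All tests in this part were chosen after the values had been seen. Not all gene lists moved more than random lists of like expression. Between e14.5 and P0, 14 of 32 lay within the central 95%: splicing (percentile 2.99), chromatin remodelling (4.68), unfolded protein and heat shock (6.56), meninges (8.23), endothelium (21.4), choroid plexus (51.4), inhibitory neurons (79.97), axon guidance (80.2), p53 targets (80.3), microglia (86.5), deep-layer neurons (91.0), cholesterol synthesis (91.5), autism-associated genes (95.6) and the interferon response (96.0). Between P0 and adult 7 did: deep-layer neurons (3.88), autism-associated genes (6.11), upper-layer neurons (6.21), blood cells (31.1), p53 targets (67.0), endothelium (78.0) and the interferon response (94.8).

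The lists not described so far are given here whether or not they differed. Between e14.5 and P0, 15 of 32 cytosolic ribosomal protein genes were lower and 1 higher (median −0.57), and between P0 and adult 11 were lower and 0 higher (median −0.75), with the reservation on shared reads. Without e14.5 library 7, 2 were higher at P0. Of 32 oxidative phosphorylation genes, 8 were lower and 3 higher at P0 than at e14.5 (median −0.26), and 14 were lower with quantile normalization. Of 30 axon guidance genes, 6 were higher and 3 lower at P0 (median 0.06). Cholesterol synthesis genes were higher at P0 in 4 of 19 and lower in 0 (median 0.26). Of 19 unfolded protein and heat shock genes, 2 were higher and 5 lower at P0 (median −0.22), and 8 were higher and 1 lower in adults (median 0.46), with Hspa1b at 3.28. Of 24 genes of REST and its targets, 13 were higher and 3 lower in adults (median 1.18), or 6 lower without adult library 1. Of 18 p53 targets, 4 were higher and 5 lower at P0 (median 0.09), and 5 higher and 4 lower in adults (median 0.09). Of 7 interferon response genes, 1 was higher at P0 (Stat2) and 4 in adults, with H2-K1 at 2.08. The count at P0 was 3 without e14.5 library 7, and 2 without P0 library 7 or with either scaling.

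Among markers of other cells and regions, inhibitory neurons had 5 of 21 members higher and 5 lower at P0 (median 0.14), with the adult counts given above. Of 11 deep-layer cortical markers, 2 were higher and 4 lower in adults (median −0.61), or 7 lower without adult library 1. Of 11 upper-layer markers, 1 was higher and 4 lower (median −0.59). Endothelial and pericyte genes had 3 of 16 higher and 3 lower at P0 (median −0.23), and 4 higher and 1 lower in adults (median 0.28). Without adult library 1, or without P0 library 1, 3 of them were lower. Microglial markers had 2 of 14 higher at P0 and 0 lower (median 0.22). Of 8 choroid plexus genes, 1 was higher at P0, and in adults 1 was higher and 1 lower (median −1.74). The median at P0 (0.01) has no firm direction: it was −0.13 with a mean above 0, −0.10 with quantile normalization, and −0.07 to −0.01 with any of 10 of the 20 libraries left out. Without e14.5 library 3, 2 of them were lower at P0. Of 15 meningeal genes, 1 was higher and 2 lower at P0 (median −0.35), and 4 were lower in adults (median −1.36), or 7 without adult library 1. Of 14 thalamic and hypothalamic genes, 4 were lower at P0 (median −1.17). In adults 1 was lower and 1 higher (median −3.27), or 9 lower without adult library 4 and 2 without adult library 1, P0 library 7 or P0 library 8. Of 7 olfactory genes, 2 were higher and 1 lower at P0 (median 1.0), and 2 were lower in adults (median −1.48). The 5 blood cell genes overlapped between P0 and adult, where the list's median was −2.99 at both ages. The midbrain and hindbrain list and the list for eye, pituitary and muscle had 2 members each in the table, and differed by −0.90 and −0.06 at P0 and by −2.17 and −1.98 in adults. The sign of the second list turned: with a mean above 0 it differed by 1.57 at P0 and 1.27 in adults, with a pseudocount of 1 by 0.05 in adults, and without P0 library 2, 7 or 10 by 0.0056 at P0. At those sizes neither list gives a direction.

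Chd8 values lay apart within some stages. In adults they were 4.10, 3.42, 3.18, 3.08, 4.15 and 4.03 for libraries 1 to 6, with a gap of 0.61 between the 3 lowest and the 3 highest. At e12.5 they were 4.19, 4.96, 4.44, 3.90, 4.12, 4.65, 4.14 and 4.75. At e14.5 they were 4.69, 4.19, 3.97, 4.01, 4.06, 3.89, 4.0, 3.62 and 4.01. At e17.5 they were 3.93, 4.47, 4.50, 4.05, 3.70, 3.87, 3.93, 3.94, 4.45 and 3.86, with a gap of 0.40 below the 3 highest. At P0 they were 4.14, 4.30, 4.60, 3.69, 3.81, 3.78, 4.40, 4.01, 3.84, 4.44 and 4.46.

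The widest gap with at least 2 libraries on either side averaged 0.31 over the 5 stages. Among 2755 genes within 0.5 log2 of Chd8's mean, the median of this measure was 0.12 and Chd8 stood at percentile 98.5. This argues against the usual spread of genes of its level as the whole account, although 40 of those genes had gaps as wide, led by Tcf7l2, Mid1 and Snhg11. The study's own factor, the genotype of the animals, may account for the gap, but no label ties a library to a genotype. The column names carry a first digit code. In 5 of 5 stages every library with code 2 had less Chd8 than every library with code 1. The lowest of code 1 against the highest of code 2 ran from 4.06 against 4.01 at e14.5 to 4.03 against 3.42 in adults. This argues against differences between animals that are unrelated to the code. The widest gap lay between the codes at e12.5, at e17.5 and in adults, but elsewhere at e14.5 and P0. No label says what this code stands for, so no library was grouped by it. With 0 libraries assigned to a genotype, genotype cannot be told apart here from another factor that goes with the code. A second code went with Xist, where Xist above 0 belonged to code 2 in 4 stages and to code 1 at P0, so that code does not follow Xist in the same sense at each stage.

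The Chd8 summits piled up in a few regions. Sequence present in many copies in the genome, and few in the reference, may account for part of this. The folds are over input, which would hold the same copies, so the positions of summits alone cannot settle it. Of the 467 summits, 171 (36.6%) lay in mitochondrial DNA, unplaced sequence or the first 4000000 bp of a chromosome, which make up a small part of the genome, and the 10 highest all lay in mitochondrial DNA. The largest cluster, with 157 summits (33.6%) on chromosome 1, lay in none of these positions. Binding of Chd8 at single sites stays open for the 93 summits in clusters of 1 to 4, which were not placed against genes. Whether the list comes from 1 sample or a pool is also open.

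In the e17.5 libraries 15.4 to 22.7% of low values lay on whole steps of a read, and in e12.5 libraries 4 and 7 36.8% and 35.0%, against 100% in the other 32. The floor was taken outside e17.5. Ddx3y shared a low value of −5.87 in e17.5 libraries 8 and 10, against −5.94 in e14.5 libraries 4 to 7. Values at a floor of their own would thus count as off the steps. For e17.5 these shares therefore cannot say whether counts were fractional. Whether the counts of the 12 libraries were fractional or corrected in some way is not settled, so their values are less surely comparable with the rest.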
